A study of Homo sapiens with 36 samples.

How the data were processed

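RNA sequencing was carried out on 6 human colon cancer cell lines, each treated for 24 h with 0.5 µM JQ1 or with DMSO, the solvent. Per the labels' protocols, cells were collected in log-phase growth, RNA was isolated on columns with a DNase step, and libraries were made with a TruSeq RNA kit. The labels state neither whether the libraries kept strand nor the read length, so reads of overlapping antisense genes cannot be told apart. Each line has 3 DMSO and 3 JQ1 libraries, 36 libraries in 12 groups, and groups were taken from the labels alone. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

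The deposited values are RPKM per gene, which the authors computed. Per the submitters' processing notes, GSNAP, DESeq and limma were used, with versions not given in the sources used here. The same notes name the build NCBIM37, the name of a mouse assembly, although the cells are human and the gene identifiers are human Entrez numbers. No coordinates are printed for that reason. Symbols were matched on the Entrez number through a RefSeq gene table of the human assembly GRCh38.p14, which named 24519 of the 26468 genes in the table. All 36 value columns matched a sample, with 0 left over.

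Depth was recovered from the steps between the RPKM values. Read counts came out whole, within 0.01 read, for 23499 genes above 0 in at least 1 library, which is 100% of them, with a largest distance of 8.9e-10 read. Of the 17544 genes detected in 20 or more libraries, 100% also gave a whole length in bases. The libraries held 18.8 to 53.1 M reads in genes, with a median of 24.5 M. The divisor that the authors used in place of the total ran from 19.1 to 52.4 M. It equalled a median-of-ratios size factor in every library, at a constant ratio of 0.981. Reads per unit of divisor therefore ranged from 0.878 to 1.02 between libraries. One read of a gene of 1 kb was worth 0.0191 to 0.0524 RPKM. A listed 0 allows up to 3 reads at 95% confidence, and such floors cover counting error only. Replicates were compared on the recovered reads over genes with at least 20 reads in a pair. Chi-square per gene was 1.23 to 3.34 over the 36 replicate pairs, so no pair agreed within sampling noise and none was counted as 1 library.

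Tests were run on log2(RPKM + 0.5) for the 15542 genes with an RPKM of at least 1 in at least 3 of the 36 libraries. Fold changes are on this scale, which understates the change of genes with low values. Of the tested genes 14839 had a symbol and 703 did not, and 104 repeated another gene's values. A linear model was fitted with limma 3.58.1 in R 4.3.3 to the 12 group means over all 36 libraries, with moderated variances and a mean-variance trend. It had 24 residual and 2.97 prior degrees of freedom. The contrasts were JQ1 minus DMSO in each line, the mean of the 6 within-line differences, the F test of whether the JQ1 effect differed between lines, and the F test of differences between lines in DMSO. Tests were two-sided with Benjamini-Hochberg adjustment within each contrast, and a gene was called at an adjusted p under 0.05. Genes called with at least a 2-fold change were also counted. Values are given as mean RPKM ± SD with n = 3 per group. Means over all lines are over 18 libraries and carry no SD, and average folds come from the mean of the 6 log2 changes and not from these means. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

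Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over 29 lists in each contrast. Camera asks whether a list moved more than the other genes. It was repeated with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way. The 30 lists were BET readout genes, BET and P-TEFb genes, MYC network genes, MYC targets, ribosome biogenesis, Wnt targets, G1/S, G2/M, cell cycle inhibitors, homologous recombination, anti-apoptotic and pro-apoptotic genes, p53 targets, intestinal differentiation, epithelial junction, mesenchymal and neuroendocrine genes, NF-kB targets, interferon-stimulated genes, MAPK output, cholesterol synthesis, lysosome and autophagy, histones, heat shock, ATF4 and ER stress, ribosomal proteins, housekeeping genes, and markers of fibroblasts, leukocytes and endothelium. Listed symbols that were not matched include CASC11, HIST1H2BC, HIST1H2BE and HIST1H2BG. None of the 5 endothelial markers passed the filter, so that list was not tested. The relation of baseline level and JQ1 response was tested over the 6 lines with exact permutation of pairings. The relation of CCAT1 and MYC was chosen because published work on these lines had raised it, so its test is not an independent one.

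The groups, tests, lists, named genes' rule and alternative settings were fixed before the data were examined. The rule always names MYC, CCAT1, HEXIM1, SERPINI1, BRD2, CDKN1A and FOSL1. For the average it takes the 10 largest rises and the 10 largest falls among called genes with 1 sign in all 6 lines. For each line it takes the 4 largest rises and the 4 largest falls among called genes whose 3 JQ1 values lie on one side of the 3 DMSO values. For the difference between lines it takes the 8 called genes with the largest range, and for each called list up to 4 members with the smallest adjusted p. Genes without a symbol, or with a mean under 1 RPKM in both groups, were passed over. Members that moved against the rest of a called list, and members of lists that were not called, are also named. Those genes were chosen after their values were seen.

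The alternative settings were pseudocounts of 0.1 and 1, no filter, a filter on the mean RPKM, median, trimmed mean and quantile scaling, the replicate number as a block, each line fitted alone, robust moderation, the cell line as the unit, each line or library left out, and other list tests. Chosen after the data were seen were limma's voom on the recovered reads, RPKM with the total reads as divisor, and one value per measurement. The steps were tested on simulated data with 50 changed genes per size among 15542. For the average contrast, 46, 49, 50 and 50 genes changed by 1.2, 1.5, 2 and 4-fold were called, with 7 false calls. For HCT116 these were 30, 48, 49 and 50, with 11 false calls. Among the single lines COLO320 had the fewest called at 1.2-fold, 27, and HCT-15 the most false calls, 16. Of simulated lists, the 1 moved list was called and 0 of 20 unchanged lists were. The simulated noise was independent between genes, so this does not test false list calls that arise from correlated genes. Sex-linked transcripts and some single list members are not reported here, and splicing and unmapped reads were not analysed here.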

Results

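Transcript levels were measured in 6 human colon cancer cell lines, HCT116, SW480, HT-29, COLO205, HCT-15 and COLO320, after 24 h with 0.5 µM JQ1 or with DMSO. JQ1 is a small molecule that occupies the acetyl-lysine pocket of the BET bromodomain proteins, readers of acetylated chromatin that promote transcript elongation. COLO320 is known for amplified copies of MYC. Each line had 3 DMSO and 3 JQ1 libraries. Reads in genes numbered 18.8 to 53.1 M per library, and 15542 genes were tested. Unless stated otherwise, folds were taken after 0.5 was added to RPKM. Where a value is low, they are smaller than the ratio of the printed RPKM. Replicates correlated at r = 0.996 to 0.998 across genes, and genes are not independent of each other.

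MYC, the growth-promoting transcription factor (Entrez 4609), fell in every line. Its level went from 1849 ± 13 to 1176 ± 6.77 RPKM in COLO320 (SD, n = 3), from 189.8 ± 5.21 to 104.8 ± 1.62 in HCT116 and from 108.9 ± 1.54 to 42.56 ± 0.866 in HT-29. COLO205 went from 64.05 ± 0.344 to 27.09 ± 0.547 RPKM and HCT-15 from 86.43 ± 1.11 to 51.15 ± 2.41. In SW480 the fall was small, from 75.85 ± 1.56 to 68.57 ± 0.472 RPKM. MYC was thus 1.11-fold lower in SW480 and 2.54-fold lower in HT-29, and 1.78-fold lower on average (adjusted p = 3.52e-32). The size of the change differed between lines (adjusted p = 8.69e-22).

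CCAT1 (Entrez 100507056), a long noncoding RNA transcribed near MYC, had its largest falls on the log2 scale where it was most abundant. The constant added to RPKM limits how far a low value can fall, so this order is partly built in. In HT-29 it went from 27.88 ± 0.313 to 0.8582 ± 0.0678 RPKM (SD, n = 3), a 20.9-fold fall, and in COLO205 from 6.393 ± 0.291 to 0.2272 ± 0.0308, 9.48-fold. HCT116 went from 2.918 ± 0.263 to 0.1664 ± 0.029 RPKM and HCT-15 from 1.833 ± 0.175 to 0.2891 ± 0.0301. COLO320 and SW480 held little CCAT1 in DMSO, 0.3278 ± 0.0571 and 0.09737 ± 0.0583 RPKM. The changes there were small on the log2 scale, by −0.24 (adjusted p = 0.00244) and −0.20 (adjusted p = 0.00933). In SW480 the values rest on 20 reads over the 3 DMSO and 4 reads over the 3 JQ1 libraries. From so low a start the added constant leaves little room for a larger fall. The small change in SW480 therefore does not show a weak response of CCAT1. The log2 change of CCAT1 in SW480 no longer passed the test without SW480 DMSO replicate 1 (adjusted p = 0.0585) or replicate 3 (adjusted p = 0.0644), under quantile scaling (adjusted p = 0.393) or with each line fitted alone (adjusted p = 0.054). Quantile scaling also ended the log2 change of CCAT1 in COLO320 (adjusted p = 0.665).

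HEXIM1 (Entrez 10614), the inhibitor of the elongation kinase P-TEFb, rose 2.09-fold in HCT-15 to 6.35-fold in COLO205, where it went from 8.765 ± 0.392 to 58.28 ± 1.01 RPKM (SD, n = 3). The average rise was 3.45-fold (adjusted p = 2.86e-38). SERPINI1 (Entrez 5274), a secreted protease inhibitor, rose 3.24-fold on average, with 11.56 ± 0.621 against 33.54 ± 0.499 RPKM in COLO320. BRD2 (Entrez 6046), itself a BET protein, rose 1.32-fold to 1.89-fold. The CDK inhibitor CDKN1A (Entrez 1026) rose from 6.97 ± 0.383 to 60.05 ± 0.85 RPKM in HCT-15, 8.11-fold, and from 2.774 ± 0.0733 to 14.67 ± 0.302 in HT-29, 4.63-fold. It stayed under 1 RPKM in COLO320, at 0.1126 ± 0.044 and 0.3951 ± 0.0193. FOSL1 (Entrez 8061), a subunit of AP-1, fell 6.16-fold in COLO205, from 32.15 ± 1.23 to 4.809 ± 0.49 RPKM, and 4.85-fold in HT-29. In SW480 it fell 2.33-fold and in HCT116 1.5-fold.

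In HCT-15 FOSL1 was slightly higher with JQ1, 15.13 ± 0.823 against 13.42 ± 0.385 RPKM (SD, n = 3; adjusted p = 0.00857). The log2 change of FOSL1 in HCT-15 did not pass with total reads as divisor (adjusted p = 0.47), at a pseudocount of 0.1 (adjusted p = 0.0772), under quantile scaling (adjusted p = 0.0641) or without HCT-15 JQ1 replicate 2 (adjusted p = 0.067). COLO320 held 11 FOSL1 reads over its DMSO libraries and 3 over its JQ1 libraries (adjusted p = 0.0219). The log2 change of FOSL1 in COLO320 was lost without DMSO replicate 1 (adjusted p = 0.0616), DMSO replicate 3 (adjusted p = 0.0585) or JQ1 replicate 1 (adjusted p = 0.109), at a pseudocount of 1 (adjusted p = 0.181) and with median centring (adjusted p = 0.0901).

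**Figure D1:**
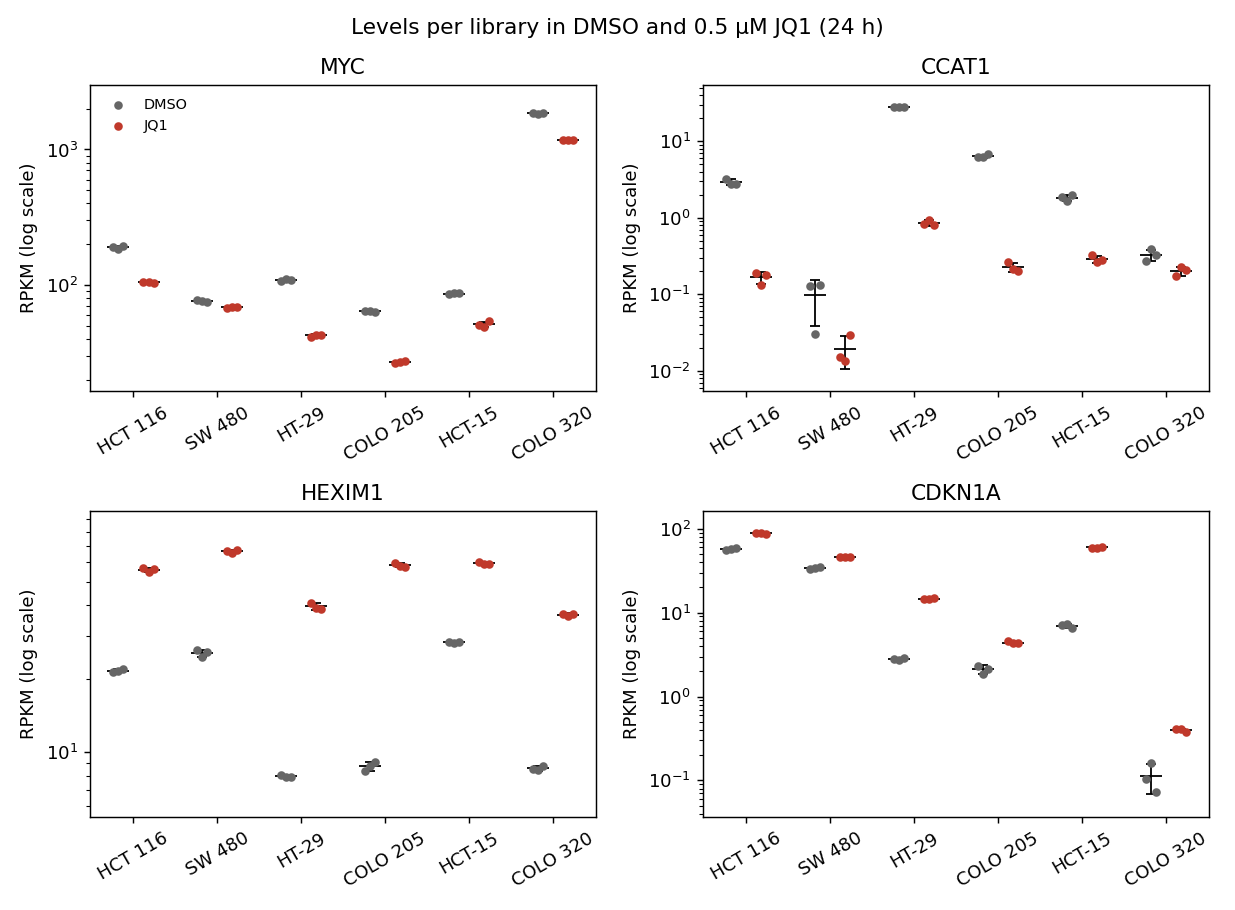
RPKM of MYC, CCAT1, HEXIM1 and CDKN1A (log axes) in each library, with DMSO in grey and JQ1 in red for the 6 lines; horizontal bars are means and error bars SD (n = 3). MYC and CCAT1 lie lower and HEXIM1 and CDKN1A higher with JQ1 in all 6 lines, and the difference for MYC is smallest in SW480.

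Averaged over the lines, most of the largest rises with JQ1 were those of histone genes. Of the 10 largest rises that had 1 sign in all 6 lines, 9 were histone genes: H2BC5, H3C10, H2BC21, H2AC6, H2BC4, H1-2, H2AC11, H2BC8 and H2AC7. H2BC5 went from a mean of 5.931 RPKM over the DMSO libraries to 50.6 over the JQ1 libraries, with an average rise of 9.13-fold, and the linker histone H1-2 from 37.18 to 242.1, 6.4-fold. Average folds are means of the log2 changes within lines, so they differ from the ratio of these means. Histone genes share near-identical copies, and how reads were divided between them is not given in the sources used here, so single members are uncertain. The remaining 1 of these 10 rises was that of DPYSL3, a cytoskeletal regulator, 5.14-fold higher on average and ahead of H2AC7 (4.8-fold). The largest fall was that of GTF3C6, a subunit of the RNA polymerase III factor TFIIIC, from 31.02 to 6.393 RPKM, 4.61-fold, with log2 changes of −2.47 to −1.99 over the lines. ACSL5, which activates fatty acids, fell 4.16-fold and CCAT1 3.99-fold. They were followed by KCTD15, BHLHA15, TYRO3, TRIP6, SLC12A8, SLC38A5 and ZNF532, 3.91-fold to 3.49-fold lower. Among these, TYRO3 is a receptor tyrosine kinase, TRIP6 an adhesion adaptor, SLC38A5 an amino acid transporter and BHLHA15 a secretory cell transcription factor. Some of the averages rest mostly on some of the lines. Log2 changes over the lines ran from −3.72 to −0.07 for ACSL5, −4.76 to −0.11 for SLC38A5, −4.39 to −0.20 for CCAT1 and 0.23 to 4.90 for DPYSL3. Adjusted p for the 20 genes was 2.45e-35 to 1.94e-20. With the cell line as the unit, GTF3C6 had an adjusted p of 3.94e-05, MYC 0.00339, CCAT1 0.02, CDKN1A 0.0201, SLC38A5 0.0376 and FOSL1 0.0427.

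Some gene lists moved more than other genes in the list test. Of 29 lists tested for the average, 5 rose and 6 fell. When treatment was exchanged within lines, 18 of 100 splits, the real one included, called at least 11 lists. Splits with 9 JQ1 libraries on each side called up to 9. Chance can therefore not be excluded for the number of list calls, and list calls in single lines were not tested in this way. All 11 histone genes tested rose at least 2-fold (median log2 change 2.52, adjusted p = 4.07e-06), and 6 of 7 BET readout genes rose, by a median of 1.89 (adjusted p = 0.00482). The exception was ZMYND8, a chromatin reader, which fell by 1.41 on the log2 scale and was lower in each of the 6 lines. The readout list shares 4 members with the histone list and HEXIM1 with the P-TEFb list, so these lists are not independent. Of 15 BET and P-TEFb genes 13 rose, led by HEXIM1, BRD2, AFF4 (0.64) and AFF1 (0.52), while HEXIM2 (−0.66) and LARP7 (−0.16) fell (adjusted p = 0.00109). Of 21 lysosome and autophagy genes 18 rose, among them the sialidase NEU1 (1.56), MAP1LC3B (1.06), the autophagy receptor SQSTM1 (0.95) and cathepsin B, CTSB (0.65), with an adjusted p of 1.69e-05. TFEB, a transcription factor that switches such genes on, fell (−0.86), as did UVRAG (−0.24) and HEXA (−0.10). Of 16 cell cycle inhibitors 11 rose, led by CDKN1A, CDKN2D (1.14), CDKN2B (1.02) and BTG1 (0.59), and RBL1 (−0.40), CDKN2A (−0.14) and RBL2 (−0.07) fell (adjusted p = 0.00482).

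Growth and replication genes fell. Of 25 MYC targets 24 fell (median −0.58, adjusted p = 1.54e-07), with the folate carrier SLC19A1 (−1.54), the kinase NME1 (−0.97), PAICS (−0.79) and RCC1 (−0.58) in front. ODC1, the polyamine enzyme, rose by 0.04. Of 30 ribosome biogenesis genes 28 fell (adjusted p = 1.54e-07), led by MRTO4 (−0.83), TCOF1 (−0.96), NCL and DKC1 (−0.63), while RRN3 and RRP12 were at 0.02. All 20 G1/S genes fell (median −0.58, adjusted p = 2.27e-07), among them the helicase subunits MCM5 (−1.10), MCM2 (−0.77), MCM7 (−0.68) and MCM3 (−0.61). Of 15 homologous recombination genes 14 fell (adjusted p = 0.000112), including FANCD2 (−0.97), TOPBP1 (−0.65) and CHEK1, and BRCA2 rose by 0.04. Of 18 G2/M genes 12 fell, with FOXM1 (−0.78), AURKA (−0.75), CCNA2 (−0.64) and BUB1B (−0.60) in front. CDC20, CENPE, BUB1 and KIF11 rose by 0.04 to 0.13 on the log2 scale (adjusted p = 0.0472 for the list, and adjusted p = 0.282 with an estimated correlation). Of 17 intestinal differentiation genes 14 fell, such as CEACAM1 (−0.97), CDH17 (−0.84), SPDEF (−0.77) and FABP1, and CDX2 (0.61) and KRT20 (0.45) rose (adjusted p = 0.0389, and adjusted p = 0.0898 with an estimated correlation). In single lines 12 of the 17 fell in HT-29 and in COLO205, and 4 to 7 in each of the other 4. The other 9 list calls held with an estimated correlation, at adjusted p of 0.00599 to 0.0283. With the cell line as the unit fewer members passed, with 3 of 17 intestinal differentiation, 7 of 18 G2/M, 11 of 15 homologous recombination, 15 of 20 G1/S, 17 of 25 MYC target and 23 of 30 ribosome biogenesis genes lower. In that form 7 of 15 P-TEFb, 8 of 16 cell cycle inhibitor and 13 of 21 lysosome genes were higher, and histone and BET readout genes kept 11 of 11 and 6 of 7.

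The remaining 18 lists were not called for the average. Counts of members that rose and fell were 4 and 10 of 15 for MYC network genes (adjusted p = 0.18), 8 and 11 of 20 for Wnt targets (0.897), 2 and 7 of 9 for anti-apoptotic genes (0.18) and 6 and 9 of 16 for pro-apoptotic genes (0.904). They were 11 and 6 of 17 for p53 targets (0.104), 8 and 4 of 13 for epithelial junction genes (0.132), 3 and 5 of 9 for mesenchymal genes (0.723) and 1 and 11 of 14 for NF-kB targets (0.0698). MAPK output genes had 7 and 9 of 17 (0.665), cholesterol synthesis 6 and 13 of 19 (0.18), ATF4 and ER stress genes 4 and 9 of 14 (0.18), and housekeeping genes 7 and 3 of 10 (0.0778). Of 3 fibroblast markers 0 rose and 3 fell (0.204), all 3 in COLO320, while 0 fell in each of the other 5 lines, and of 4 leukocyte markers 1 rose and 2 fell (0.723). For the last 4 lists the direction depended on the measure. Heat shock genes, 5 and 4 of 9, had a median of 0.13 and a mean of −0.08 (0.904). Neuroendocrine genes, 6 and 2 of 8, had a median of 0.139 and a mean of −0.002 (0.51). Interferon-stimulated genes, 7 and 9 of 18, had a median of −0.22 and a test in the upward direction (0.998). Ribosomal protein genes, 6 and 6 of 15, had a median of 0.01, which turned negative under quantile and total-read scaling (0.65). Counts adjusted over the list alone were the same for each list except epithelial junction genes, with 9 rather than 8 rises.

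**Figure D2:**
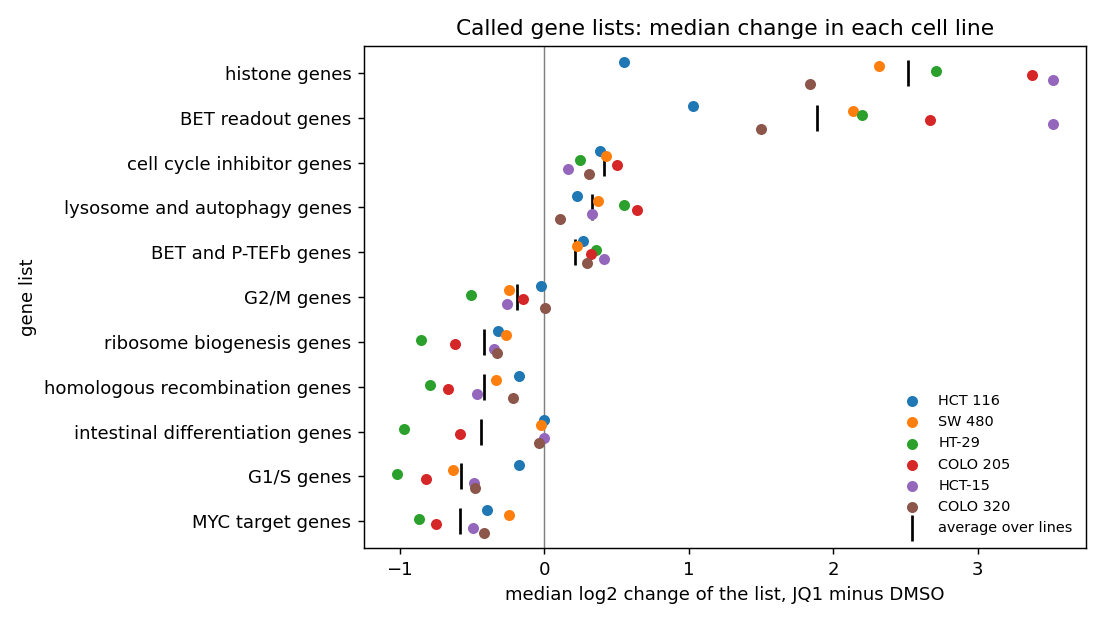
Median log2 change (JQ1 minus DMSO) of the 11 gene lists called for the average, one dot per cell line and a black bar for the average over lines. Histone and BET readout genes lie furthest to the right, at 2.52 and 1.89 on average, and MYC targets and G1/S genes furthest to the left, both at −0.58.

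In numbers of genes, the response was broad and mostly small. Between 4824 and 5694 genes rose and between 5503 and 6225 fell in a single line, and 6245 rose and 7500 fell on average. At 2-fold or more, 637 rose and 917 fell in HT-29, 542 and 875 in COLO205, 502 and 758 in SW480, 527 and 552 in HCT-15, 220 and 488 in HCT116, and 188 and 724 in COLO320. The average gave 207 and 288. With the cell line as the unit 2893 genes rose and 3162 fell. Counts at 2-fold depend on the pseudocount, and voom on the recovered reads gave 471 and 1093 for the average, 463 and 1467 for COLO320 and 1130 and 1622 for HT-29.

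**Figure D3:**
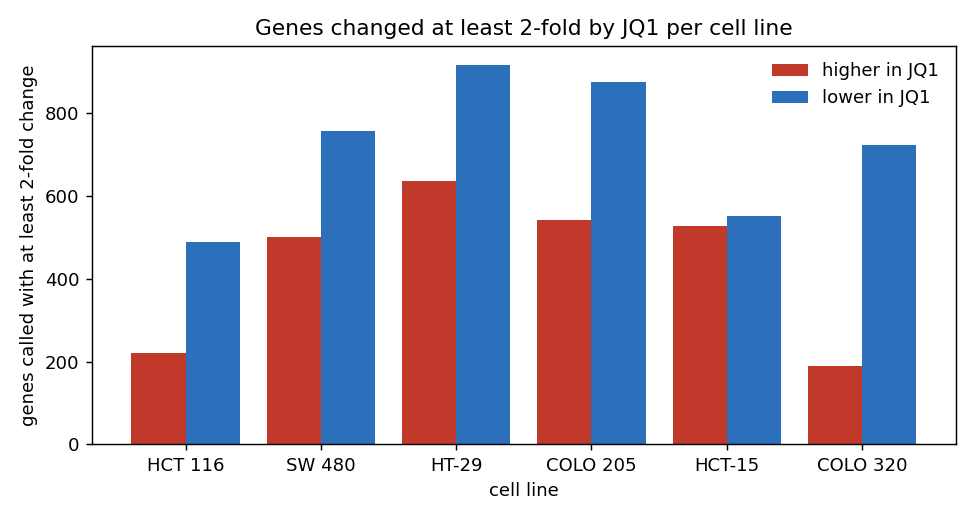
Number of genes called with at least a 2-fold change in each cell line (15542 tested), red for higher and blue for lower with JQ1. HT-29 has the most, 637 higher and 917 lower, and HCT116 the fewest lower, 488.

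In HCT116, JQ1 raised DHRS2, a mitochondrial reductase, from 6.158 ± 0.682 to 91.23 ± 1.91 RPKM (SD, n = 3), 13.8-fold, and the metallothionein MT2A from 550.7 ± 22.5 to 3155 ± 28.9. CLIC3 (8.2-fold) and TEX14 (5.96-fold) completed the 4 largest rises. Keratin KRT7 fell from 32.75 ± 1.82 to 1.143 ± 0.0627 RPKM, 20.2-fold, followed by ADGRF1 (14.5-fold), ACSL5 (13.2-fold) and ARL14EPL (10.7-fold). Genes of cholesterol synthesis fell, 16 of 19, with STARD4 and SREBF2 (−0.73) among those lower (adjusted p = 1.73e-06). MYC targets fell in 22 of 25 cases (adjusted p = 3.35e-06), with ODC1, EIF4A1 and LDHA higher, and ribosome biogenesis genes in 23 of 30 with 0 higher (adjusted p = 6.35e-06). Of 16 cell cycle inhibitors 12 rose, led by RB1 (0.50) and CDKN2D (1.23), and RBL2 and CDKN2A fell (adjusted p = 0.00571). These 4 calls held with an estimated correlation.

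Another 7 lists in HCT116 did not hold in that form. NF-kB targets fell in 9 of 14 cases, led by TNFAIP2, ICAM1 and RELB (−1.19), with SOD2 higher (adjusted p = 0.0406, and adjusted p = 0.0751 with an estimated correlation). ATF4 and ER stress genes fell in 11 of 14, with SLC7A11 (−1.39) and TRIB3 (−1.36), while ASNS (1.17) and HERPUD1 (0.07) rose (adjusted p = 0.00571, and adjusted p = 0.171 with an estimated correlation). Histone genes rose in 7 of 11, and in 8 when adjusted over the list alone, and lysosome genes in 14 of 21 with HEXA, TFEB, WIPI1 and UVRAG lower (both adjusted p = 0.00571, and adjusted p = 0.106 with an estimated correlation). BET readout genes rose in 5 of 7, and in 6 when adjusted over the list alone, with ZMYND8 lower, and P-TEFb genes in 10 of 15 with HEXIM2, LARP7 and CCNT2 lower (adjusted p = 0.0385 and 0.00582, and for both adjusted p = 0.0751 with an estimated correlation). Housekeeping genes rose in 8 of 10, with GAPDH leading and TFRC and TBP lower (adjusted p = 0.018, and adjusted p = 0.171 with an estimated correlation).

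SW480 cells raised ART5, an ADP-ribosyltransferase, from 0.1884 ± 0.0355 to 22.5 ± 1.27 RPKM (SD, n = 3), 33.4-fold, and DHRS2 from 32.73 ± 0.818 to 494 ± 6.74. The histone genes H4C8 (17.6-fold) and H2BC8 (14.1-fold) were the other two of the 4 largest rises. The largest falls were those of the kinase ZAP70 (10.3-fold), the cytokine IL10 (8.8-fold), the channel TRPV2 (8.55-fold) and the decoy receptor TNFRSF11B (7.94-fold). Here ATF4 and ER stress genes rose, 12 of 14, with asparagine synthetase ASNS from 67.4 ± 1.59 to 530.5 ± 2.62 RPKM, PSAT1 (1.16), PHGDH (0.77) and ATF4 (0.57), and HSPA5 and XBP1 lower (adjusted p = 6.64e-05, and adjusted p = 0.0651 with an estimated correlation). All 20 G1/S genes fell (adjusted p = 5.03e-08) and all 11 histone genes rose (adjusted p = 7.44e-07). Of 17 p53 targets 13 rose, among them FDXR (1.03), TP53INP1 (1.36) and XPC (0.62), and BAX, FAS and MDM2 fell (adjusted p = 0.00652). BET readout genes rose in 6 of 7 (adjusted p = 0.00388), lysosome genes in 16 of 21 with TFEB, HEXA, UVRAG and CTSD lower (adjusted p = 0.000563), and homologous recombination genes fell in 14 of 15 with BRCA2 higher (adjusted p = 0.000527).

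A further 10 lists in SW480 were, like the ATF4 list, called only with the preset correlation. MAPK output genes fell in 13 of 17, such as ETV4 (−1.31), SPRY4 (−1.23) and PHLDA1 (−1.10), and EGR1, ETV5 and EPHA2 rose, 3 genes and 4 when adjusted over the list alone (adjusted p = 0.0158, and adjusted p = 0.0724 with an estimated correlation). Cholesterol synthesis genes rose in 12 of 19, with LSS (1.03), INSIG1 (0.77) and SQLE (0.61), and genes such as FDPS and STARD4 fell (adjusted p = 0.0157, and adjusted p = 0.213 with an estimated correlation). MYC targets fell in 19 of 25, with MTHFD2 (0.86), ODC1, SHMT2, LDHA and PPAT higher, and ribosome biogenesis genes in 20 of 30, with RRN3, RRP12, BOP1 and POLR1A higher (both adjusted p = 0.00388, and adjusted p = 0.0776 and 0.0651 with an estimated correlation). NF-kB targets fell in 10 of 14, led by NFKB1 (−0.96), ICAM1 (−1.43) and LTB (−1.81), with SOD2 higher (1.28), and anti-apoptotic genes in 7 of 9, led by XIAP (−0.63), with MCL1 higher (adjusted p = 0.0371 and 0.0263, and adjusted p = 0.0687 and 0.0651 with an estimated correlation). G2/M genes fell in 13 of 18, with CENPE, BUB1, KIF20A and KIF11 higher (adjusted p = 0.0169, and adjusted p = 0.213 with an estimated correlation). Cell cycle inhibitors rose in 11 of 16, led by BTG1 (0.97) and CDKN2B (1.09), with RBL1, RBL2, CDKN2A and CDKN1C lower, and P-TEFb genes in 11 of 15, with LARP7, HEXIM2 and CCNT2 lower (adjusted p = 0.0221 and 0.0107, and adjusted p = 0.0743 and 0.0724 with an estimated correlation). Ribosomal protein genes had 11 of 15 higher, 12 when adjusted over the list alone, with RPL6 and RPS24 lower (adjusted p = 0.0188, and adjusted p = 0.34 with an estimated correlation).

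In HT-29 the largest falls, ranked with 0.5 added to RPKM, were those of 4 single genes. TM4SF4 fell from 305 ± 3.02 to 6.787 ± 0.602 RPKM (SD, n = 3), 42-fold, the pore-forming claudin CLDN2 from 27.01 ± 0.145 to 0.1747 ± 0.0352, 40.8-fold, the annexin ANXA13 32.4-fold and SLC38A5 27.2-fold. DPYSL3 rose from 0.4782 ± 0.0662 to 28.75 ± 1.06 RPKM, 29.9-fold, followed by H2BC5, H2AC6 and H2BC4 at 22.5-fold to 22.9-fold. All 25 MYC targets fell, 10 of them at least 2-fold, with NME1 from 214.9 ± 7.21 to 60.84 ± 0.798 RPKM, HK2 (−2.77), SRM (−1.90) and PAICS (−1.35) in front (adjusted p = 1.15e-12). All 20 G1/S genes (adjusted p = 3.13e-11), 18 G2/M genes (adjusted p = 1.26e-07) and 15 homologous recombination genes (adjusted p = 3.15e-07) fell as well, as did 28 of 30 ribosome biogenesis genes, with RRN3 and UBTF higher (adjusted p = 2.72e-12). Of 17 intestinal differentiation genes 12 fell, 13 when adjusted over the list alone, led by the goblet cell factor SPDEF (20.56 ± 0.567 to 1.361 ± 0.116 RPKM), FABP1, CDX1 (−1.17) and ATOH1 (−1.62), and KRT20 (1.07), DPP4 and CDX2 rose (adjusted p = 0.00486). Epithelial junction genes rose in 9 of 13, with KRT18 from 1660 ± 25.9 to 4145 ± 9.26 RPKM and KRT8 from 1201 ± 16 to 2868 ± 36.8, and ESRP1, CLDN7 and EPCAM lower (adjusted p = 0.00344). Lysosome genes rose in 19 of 21, with SQSTM1 (1.37), MAP1LC3B (1.54) and NEU1, and TFEB and UVRAG lower (adjusted p = 5.25e-07). Histone genes rose in 10 of 11, with H1-4 at 0.17 (adjusted p = 6.3e-06), BET readout genes in 6 of 7 (adjusted p = 0.00351) and P-TEFb genes in 10 of 15 with HEXIM2 and LARP7 lower (adjusted p = 0.00349). Cholesterol synthesis genes fell in 12 of 19, with HMGCS1 (−1.03) among them, and SC5D and LSS higher (adjusted p = 0.00349, and adjusted p = 0.148 with an estimated correlation).

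In COLO205 enzymes made up the 4 largest falls of single genes. BAAT, the bile acid conjugating enzyme, fell from 75.25 ± 2.28 to 0.8689 ± 0.173 RPKM (SD, n = 3), 55.6-fold, PCK1, the gluconeogenic enzyme, from 49.9 ± 0.628 to 1.135 ± 0.13, 30.9-fold, carbonic anhydrase CA9 24.2-fold and the RNA-editing enzyme APOBEC1 21.3-fold. The 4 largest rises were histone genes, H3C10 (22.7-fold), H2BC8 (17.4-fold), H2BC21 (15.1-fold) and H2BC5 (14.8-fold). Of 17 intestinal differentiation genes 12 fell, among them GPA33 (172.1 ± 2.47 to 7.76 ± 0.137 RPKM), FABP1 (−3.93) and CEACAM1 (−2.08), while the intestinal transcription factor CDX2 rose from 0.3304 ± 0.118 to 9.898 ± 0.458 RPKM and KRT20 by 0.28 (adjusted p = 0.00857). ATF4 and ER stress genes fell in 12 of 14, with the chaperone HSPA5 from 635.8 ± 4.48 to 194.3 ± 2.96 RPKM, HERPUD1 (−1.71), PSAT1 (−1.95) and ATF4 (−0.96), and ATF3 rose (adjusted p = 9.73e-06). All 25 MYC targets (adjusted p = 1.13e-11), 20 G1/S genes (adjusted p = 2.6e-10) and 15 homologous recombination genes (adjusted p = 3.59e-06) fell, with SLC19A1 at −2.89 and E2F2 at −2.37. Ribosome biogenesis genes fell in 28 of 30, with RRP12 and POLR1A higher (adjusted p = 3.64e-09). Of 16 cell cycle inhibitors 10 rose, led by CDKN1C (0.8627 ± 0.142 to 15.85 ± 0.595 RPKM) and CDKN1B (0.63), and RBL1 and BTG1 fell (adjusted p = 0.00857). Histone genes rose in 11 of 11 (adjusted p = 3.5e-07), lysosome genes in 19 of 21 with UVRAG and TFEB lower (adjusted p = 1.77e-07), P-TEFb genes in 13 of 15 (adjusted p = 8.48e-05) and BET readout genes in 6 of 7 (adjusted p = 0.00199). Wnt targets rose in 13 of 20, with NKD1 (1.41), BMP4 (0.96) and AXIN2 (0.73) higher and CRIPTO (−2.61) lower (adjusted p = 0.0325, and adjusted p = 0.132 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 19, with LSS, SREBF1 and MVD higher (adjusted p = 0.00861, and adjusted p = 0.203 with an estimated correlation).

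In HCT-15 MAPK output genes rose, unlike in the other 5 lines, and so did epithelial junction genes. KRT8 went from 558.4 ± 1.7 to 2110 ± 14.7 RPKM (SD, n = 3), KRT18 from 840.5 ± 11.5 to 2828 ± 21.4 and KRT19 from 274.2 ± 3.79 to 1410 ± 13.4. They led the epithelial junction list, with 9 of 13 higher and ESRP1 and GRHL2 lower (adjusted p = 0.00447). MAPK output genes rose in 12 of 17, with the phosphatase DUSP6 from 4.69 ± 0.341 to 18.47 ± 0.57 RPKM, FOS from 2.245 ± 0.204 to 17.91 ± 0.236, EPHA2 (1.43) and DUSP5 (1.80), while EREG (−1.65), ETV4 (−1.14) and SPRY2 (−0.20) fell (adjusted p = 0.00563). Histone genes made up the 4 largest rises, H1-2 from 11 ± 1.06 to 180.6 ± 4.49 RPKM, 15.8-fold, H2BC5 (15.7-fold), H2BC4 (13.5-fold) and H2BC11 (12.6-fold), and all 11 rose (adjusted p = 3.03e-06). The largest falls were those of the glutamyltransferase GGT6 (7.42-fold), CLDN2 (6.84-fold), MAB21L4 (6.33-fold) and CA9 (6.21-fold). MYC targets fell in 21 of 25, with ODC1 (0.70), EIF4A1, LDHA and IPO4 higher (adjusted p = 7.24e-06), ribosome biogenesis genes in 26 of 30 with RRP12 higher (adjusted p = 3.57e-07), G1/S genes in 17 of 20 with RRM2 (0.71) and CCND1 (0.65) higher (adjusted p = 1.08e-05), and homologous recombination genes in 14 of 15 with BRCA2 higher (adjusted p = 2.87e-05). BET readout genes rose in 6 of 7 (adjusted p = 0.00149) and P-TEFb genes in 10 of 15 with HEXIM2 and LARP7 lower (adjusted p = 0.00293). G2/M genes fell in 16 of 18, with FOXM1 at −1.06 and CDC20 and BUB1 higher, and lysosome genes rose in 14 of 21, with TFEB, UVRAG, HEXA and CTSA lower (adjusted p = 0.00035 and 0.00293, and for both adjusted p = 0.0694 with an estimated correlation). Housekeeping genes rose in 7 of 10, with ACTB (0.75) and GAPDH (0.63), and TBP, HPRT1 and TFRC lower (adjusted p = 0.0155, and adjusted p = 0.186 with an estimated correlation). With total reads as divisor, a setting chosen after the data were seen, the median of all genes in HCT-15 moved by −0.115 on the log2 scale. The split of 5413 higher and 5503 lower genes then became 4311 and 6816, or 38.7% against 49.6% higher.

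In COLO320 the chemokine CXCL11 had the largest fall of a single gene. It fell from 8.959 ± 0.864 to 0.2319 ± 0.0958 RPKM (SD, n = 3), 13-fold, the sulfide oxidising enzyme SQOR from 54.61 ± 1.55 to 4.758 ± 0.362, 10.5-fold, MPP4 9.53-fold and the Wnt antagonist WIF1 8.63-fold. The T-box gene TBX10 rose from 0.2124 ± 0.0335 to 6.156 ± 0.301 RPKM, 9.34-fold, followed by H2BC5 (6.59-fold), H2BC21 (5.47-fold) and H2AC6 (5.21-fold). Of 6 fibroblast markers 3 passed the filter, PDGFRB through the DMSO libraries of this line alone, and all 3 fell, COL3A1 from 13.2 ± 0.112 to 2.647 ± 0.183 RPKM, PDGFRB from 1.182 to 0.1889 and COL1A1 from 1.233 to 0.2125 (adjusted p = 0.00504). COL3A1 had 0.00933 RPKM in DMSO in HCT116 and a listed 0 in the other 4 lines. Of 20 G1/S genes 18 fell, with CCND1 (−1.32) and E2F2 (−1.71), and CCNE2 (0.10) and E2F1 (−0.07) were not called (adjusted p = 2.15e-07). MYC targets fell in 21 of 25 with PPAT higher (adjusted p = 1.93e-06) and ribosome biogenesis genes in 26 of 30 with RRP12 and POLR1A higher (adjusted p = 4.44e-06). All 11 histone genes (adjusted p = 9.02e-06), 11 of 15 P-TEFb genes with HEXIM2 lower (adjusted p = 0.00087) and 6 of 7 BET readout genes (adjusted p = 0.00532) rose.

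Another 5 lists in COLO320 were called only with the preset correlation. Cell cycle inhibitors rose in 9 of 16, led by CDKN2D (2.06) and CCNG2 (1.01), and CDKN1C (−1.43), RBL1, CDKN2A and CDKN2C fell (adjusted p = 0.0303, and adjusted p = 0.128 with an estimated correlation). Lysosome genes rose in 11 of 21, with NEU1 at 1.18 and TFEB (−1.19), CTSD and UVRAG lower, and homologous recombination genes fell in 11 of 15, with BRCA2 higher (adjusted p = 0.0273 and 0.03, and for both adjusted p = 0.184 with an estimated correlation). ATF4 and ER stress genes fell in 9 of 14, with TRIB3 (−1.71), SLC7A11 and ATF4 (−0.54), and DNAJB9, SESN2, DDIT3 and ATF3 rose (adjusted p = 0.0145, and adjusted p = 0.274 with an estimated correlation). Ribosomal protein genes had 13 of 15 higher, with RPL6 and RPL13A lower (adjusted p = 0.013, and adjusted p = 0.318 with an estimated correlation).

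The lines shared part of the response. In all 6 lines 1741 genes rose and 1817 fell, where independent lists of the same sizes would share 23.1 and 41.9. At 2-fold or more in every line there were 28 rises and 30 falls, against 4.17e-06 and 0.000131. HEXIM1, SERPINI1, H2BC5, GTF3C6, KCTD15, TYRO3 and TRIP6 were among these at 2-fold or more. Each line has its own DMSO libraries, so no controls were shared. The 6 lines share an estimate of the spread for each gene, however, so a gene with little spread passes more readily in every line. The lists are therefore not independent, and the expected numbers do not measure how far the response is shared. Among genes called at 2-fold or more in either line of a pair, 74.3% to 88% changed in the same direction. Log2 changes of a pair of lines correlated across genes at r = 0.423 (COLO205 and COLO320) to 0.659 (HT-29 and COLO205) over 15 pairs.

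Much of the response also differed between lines. The JQ1 effect was called different for 14507 of 15542 genes, and 5222 genes rose in 1 line and fell in another, 79 of them at 2-fold or more in both. If the replicates are technical, these tests cannot tell the response of a line from a deviation of a single culture. The 8 widest ranges of log2 change were those of BAAT (5.77), TM4SF4 (5.43), CLDN2 (5.39), ART5 (5.29), ANXA13 (5.04), PCK1 (5.04), CDKN1C (5.02) and TBX10 (4.72), with adjusted p of 4.06e-29 to 4.79e-22. CDKN1C, a CDK inhibitor, rose 12-fold in COLO205 and fell in COLO320, from 5.052 ± 0.0321 to 1.565 ± 0.24 RPKM (SD, n = 3). TBX10 rose in COLO320 and fell in HT-29, from 2.979 to 0.7373 RPKM. TM4SF4 in COLO205 went from 2.415 RPKM to a listed 0, at least 32.7-fold lower when the floor is 3 reads per library. BAAT, TM4SF4, ANXA13 and PCK1 lay near or under that floor in several other lines, where no fold is given. CLDN2 lay under it in COLO320, TBX10 in HCT116 and HCT-15, and ART5 in the DMSO libraries of COLO205 and HT-29. ART5 rose to 22.5 RPKM in SW480 and to 4.617 in HT-29.

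Gene groups differed between lines too, each of the 29 by an interaction test on list means (largest adjusted p = 1.16e-07), with the same limit if the replicates are technical. The mean log2 change of MAPK output genes was 0.671 in HCT-15 and −0.445 to −0.196 in the other 5 lines. ATF4 and ER stress genes averaged 0.941 in SW480, 0.118 in HCT-15 and −1.05 in COLO205. Cholesterol synthesis genes averaged 0.238 in SW480 and −0.618 in HCT116. Intestinal differentiation genes averaged −0.897 in HT-29 and −0.914 in COLO205, against −0.183 to −0.129 elsewhere. G1/S genes averaged −0.983 in HT-29 and −0.191 in HCT116, and histone genes 2.97 in COLO205 and 0.85 in HCT116.

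Before treatment the lines differed widely, in 15358 of 15542 genes. MYC ranged in DMSO from 64.05 RPKM in COLO205 to 1849 in COLO320. KRT19 was at 0.04002 RPKM in COLO320 and between 274.2 and 1011 in the other lines, and CDX2 at 1099 RPKM in COLO320 and at 0.3304 in COLO205. Across the 6 lines, a higher log2 level of CCAT1 in DMSO went with a larger fall of MYC. Published work on these lines had already raised this question. Pearson's r was −0.929 (exact permutation p = 0.0139, adjusted p = 0.0278 over 2 relations, two-sided, n = 6) and Spearman's rho −1 (exact permutation p = 0.00278, adjusted p = 0.00556). Without HCT116 the Pearson r, CCAT1 level in DMSO against MYC log2 change, was −0.929 and without HCT-15 −0.928, and neither passed the exact permutation test (adjusted p = 0.0833 for both, n = 5). Without the 2 most distant lines, HT-29 and SW480, r was −0.909 (exact permutation p = 0.125, n = 4). Few pairings exist at n = 4, so this test could hardly pass and decides little. The level of MYC in DMSO had no such relation to the median change of MYC targets, with r = 0.26 (exact permutation p = 0.662, adjusted p = 0.662) and rho = 0.143 (exact permutation p = 0.803, adjusted p = 0.803). Without COLO320 and HCT116 that r was −0.325 (exact permutation p = 0.708, n = 4), again with few pairings.

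**Figure D4:**
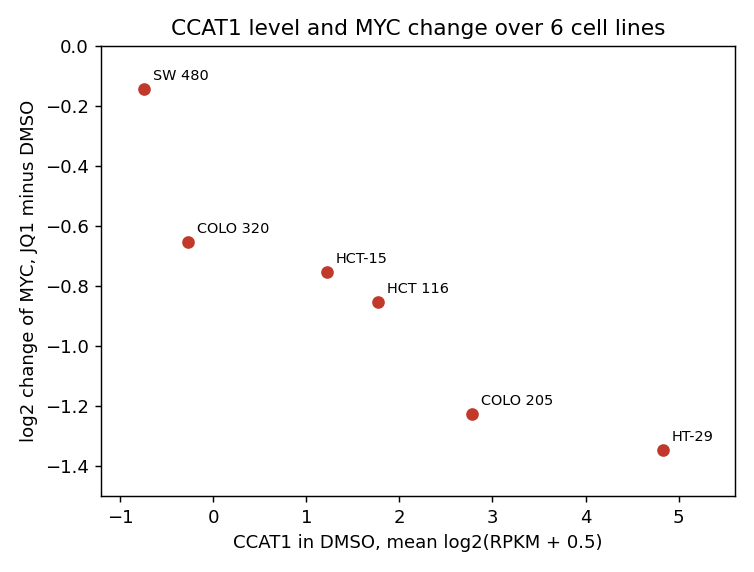
Log2 change of MYC (JQ1 minus DMSO) against the mean log2(RPKM + 0.5) of CCAT1 in DMSO, one point per cell line (n = 6). The order runs from SW480, with the least CCAT1 and a MYC change of −0.14, to HT-29, with the most CCAT1 and a change of −1.35 (r = −0.929).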

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

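The tests of S phase and of the CCAT1 relation were chosen after the result was seen, as were the counts of splits by how many JQ1 libraries fell on each side. What was singled out here is a JQ1 effect that differed between the cell lines by an interaction test. For single genes the value is the range of the log2 change over the 6 lines. It was 1.2 for MYC, 4.19 for CCAT1, 1.6 for HEXIM1, 1.3 for SERPINI1, 0.521 for BRD2, 2.6 for CDKN1A and 2.79 for FOSL1. It was 5.77 for BAAT, 5.43 for TM4SF4, 5.39 for CLDN2, 5.29 for ART5, 5.04 for ANXA13, 5.04 for PCK1, 5.02 for CDKN1C and 4.72 for TBX10. CCAT1, BAAT, TM4SF4, CLDN2, ANXA13 and PCK1 were low in some lines, where the constant added to RPKM leaves little room for a fall. Part of their range is therefore built in. For lists it is the range of the mean change, with 2.12 for histone, 1.99 for ATF4 and ER stress, 1.8 for BET readout, 1.69 for fibroblast and 1.12 for MAPK output genes. It was 0.856 for cholesterol synthesis, 0.792 for G1/S, 0.784 for intestinal differentiation, 0.755 for epithelial junction, 0.701 for neuroendocrine, 0.689 for MYC target and 0.671 for leukocyte lists. It was 0.634 for ribosome biogenesis, 0.566 for homologous recombination, 0.552 for Wnt, 0.545 for G2/M, 0.531 for lysosome, 0.517 for mesenchymal and 0.481 for MYC network genes. The lowest ranges were 0.421 for interferon-stimulated, 0.42 for pro-apoptotic, 0.391 for NF-kB, 0.382 for p53, 0.351 for anti-apoptotic, 0.34 for cell cycle inhibitor, 0.316 for P-TEFb, 0.297 for housekeeping, 0.239 for heat shock and 0.23 for ribosomal protein genes.

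Histone genes rose with JQ1 by a median of 2.52 on the log2 scale, between 0.551 and 3.52 per line. Carry-over of RNA without a poly(A) tail would raise other such transcripts, but 21 of them had a median of 0.202, with 9 higher and 6 lower. They did not move together, from −0.48 for SNORA23 to 0.84 for RNU4ATAC and 1.00 for RNU4-1. None reached the histone median, but carry-over as a part of the rise is not excluded. A length bias would raise the 5361 other genes of the same lengths, whose median was −0.0726. More cells in S phase would raise G1/S genes, whose median was −0.576. JQ1 may lower G1/S genes by itself, however, and no cell cycle measurement was used here, so S phase is not excluded. Reads shared between near-identical copies were not tested and, like S phase, stay open. One hypothesis not tested is that BET inhibition may raise the polyadenylated form of histone transcripts. Sequencing of total RNA beside poly(A)-selected RNA from the same cells would test it.

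In HCT-15 and HT-29, reads per unit of the deposited divisor rose with JQ1, by 0.123 and 0.0704 on the log2 scale. Without the 50 genes with most reads, at least 0.626 of the rise was left (0.077 and 0.0444), so these genes are not the whole cause. Without the deepest library of each group at least 1.02 of it was left, against depth as the cause. In HCT-15 the gain in reads was led by KRT8 (4.5% of it), KRT18 (3.9%) and NQO1 (3.47%), and in HT-29 by KRT18 (7.9%) and KRT8 (7.81%). Which divisor tracks RNA per cell stays open, since no spiked-in standard was used here, and changes in HCT-15 could be shifted by about the 0.115 between divisors.

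Lines with more CCAT1 had larger falls of MYC. The authors' scaling does not account for this, since r was −0.895 or lower under 4 other scalings, nor does COLO320 with its amplified MYC, since r was −0.958 without it. With 6 lines and no CCAT1 perturbation, other differences between the lines stay open and untested. Whether CCAT1 has a part in the fall of MYC was not tested, and depletion of CCAT1 before JQ1 would test it.

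Other splits of the libraries bear on chance. Within a line 10 splits are too few for a share under 0.05. The real split called 10541, 11487, 11496, 11318, 10916 and 10604 genes in HCT116, SW480, HT-29, COLO205, HCT-15 and COLO320, where the highest other split called 4, 11, 5, 2, 2 and 7. In each line the number of splits with a result as large was 1. Over 100 splits, the real one included, treatment was exchanged within lines. Only the real one, 1 of 100, reached its count for the average (13745 against a highest other of 8944). A chance division of these libraries can be excluded. If the replicates are technical, such splits do not test chance differences between cultures. The real split was also 1 of 100 for genes shared by all lines (3558 against 0), but other splits within a line call at most 11 genes, so a count near 0 is built in and excludes nothing. For differences in DMSO the real split was 1 of 100 too (15358 against 10794). There the DMSO libraries were exchanged between lines. Mixed groups then hold libraries of different lines, which widens the spread. This count therefore shows only that DMSO libraries of the same line resemble each other more than those of other lines. For the difference in effect the real split was also 1 of 100 (14507 against 8060). Those splits exchanged treatment within lines and kept each line together, so they do not test a difference between lines, which rests on the interaction F test alone. For the lists called on average 18 of 100 splits reached the 11 of the real split, with a highest other of 13, so chance cannot be excluded by this count. The split with most genes had 14 of the 18 JQ1 libraries on one side, and splits that reached 11 lists had at least 10. In the 19 splits with 9 JQ1 libraries on each side the highest counts were 9 lists and 437 genes.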

How the results depend on the processing

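Limma's voom on recovered reads, total reads as divisor and one value per measurement were chosen after the data were seen. Over all alternatives 991 counts stayed within 1.5 times their value and 34 did not, 3955 values of genes or relations kept their call and 16 lost it, and of list results 340 kept, 18 gained and 12 lost a call. With the cell line as the unit 2893 genes rose and 3162 fell on average, where only 6 differences per gene set the error. Fry called 11 lists up and 18 down and turned the direction of pro-apoptotic (median −0.147), neuroendocrine (0.139) and heat shock genes (0.13); it tests no list against other genes. Pearson's r of CCAT1 and MYC stayed at −0.929 without HCT116 and at −0.928 without HCT-15, with exact permutation p no longer under the threshold at n = 5 (adjusted p = 0.0833 for both).

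The G2/M call was lost at a pseudocount of 1, under median, trimmed mean and quantile scaling, under the replicate block and with one value per measurement, and the intestinal differentiation call at a pseudocount of 0.1, with a filter on the mean RPKM, with only members over that mean and with total reads as divisor. Without a filter p53, NF-kB and housekeeping lists passed. The cause was not tested. At 2-fold or more, a pseudocount of 0.1 gave 363 rises and 638 falls on average and 53 falls in every line, and a pseudocount of 1 gave 182 average falls and 18 rises and 18 falls in every line. For single lines a pseudocount of 0.1 gave 357 and 869 in HCT116, 326 and 1139 in COLO320 and 877 falls in HCT-15, a pseudocount of 1 gave 362 falls in HCT-15 and 116 rises in COLO320, and quantile scaling 759 rises in SW480. Voom gave 490 and 1105 in HCT116, 888 and 1366 in SW480, 974 and 1539 in COLO205, 910 and 1182 in HCT-15 and 51 and 97 in every line; it adds no constant to RPKM.

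Replicate numbers do not pair the samples. Over 18 pairs, same-numbered DMSO and JQ1 libraries deviated together at r = −0.148 to 0.0492, 0 of them over 0.1, and 4 DMSO samples were closest to their own number. With the replicate block 6213 genes rose and 7479 fell on average, 1717 and 1780 in every line, the effect differed for 14409, and 5 lists rose and 5 fell; G2/M was the only call lost. Leaving out each library in turn gave 6211 to 6239 average rises, 7469 to 7509 falls, 1712 to 1748 rises and 1789 to 1810 falls in every line. Depth limits genes near 3 reads per library, such as CCAT1 in SW480 and FOSL1 in COLO320.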

Other observations

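Several groups not called as a whole held genes that moved, some in all or most lines and others named for single lines only. These genes were chosen after their values were seen, and no further test was run. MXD4, an antagonist of MYC that shares its partner MAX, rose in all 6 lines, from 12.13 ± 0.442 to 55.66 ± 0.881 RPKM (SD, n = 3) in HT-29 and from 17.98 ± 0.256 to 43.15 ± 1.04 in COLO320. The noncoding RNA PVT1, a neighbour of MYC, fell by 0.73 on average and from 588 to 394.5 RPKM in COLO320. Cell death genes went both ways. BMF, a pro-apoptotic BCL2 family member, rose from 1.234 ± 0.109 to 14.15 ± 0.695 RPKM in HT-29 and from 0.4247 ± 0.0561 to 11.05 ± 0.181 in COLO205, and BCL2L11 rose in all 6 lines, by 0.42 to 1.52 on the log2 scale. The death receptor FAS fell by 0.68, TNFRSF10A by 0.70 and the survival factor CFLAR by 0.77 on average, while the survival factor MCL1 rose from 71.24 ± 1.58 to 169.2 ± 2.28 RPKM in HCT-15.

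Interferon genes split in a similar way. IRF7 rose in 5 lines, from 1.907 ± 0.184 to 13.07 ± 0.49 RPKM (SD, n = 3) in HCT116, and was at 0.1929 and 0.1647 RPKM in COLO320. IFIT3 fell by 0.92, OAS3 by 0.88 and IFIH1 by 0.79 on average. Among Wnt targets AXIN2 rose in 5 lines and was slightly lower in SW480, at 193 ± 3.37 and 184.5 ± 2.51 RPKM. The stem cell factor ASCL2 fell from 38.36 ± 0.681 to 8.284 ± 0.411 RPKM in HCT-15 and rose from 34.02 ± 2.23 to 70.07 ± 3.19 in COLO205. The EGFR ligand EREG fell from 226.9 ± 3.95 to 49.75 ± 0.317 RPKM in HCT116 and from 29.25 ± 1.08 to 3.282 ± 0.178 in HT-29, and in COLO320 it was at 0 and 0.002506 RPKM.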
